A study of Mus musculus with 9 samples.

How the data were processed

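The series measured messenger RNA in mouse bone marrow-derived macrophages, which are macrophages grown from bone marrow in culture. Per the labels, the mice were of the C57BL/6N strain. Cells received lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, at 100 ng/mL for 24 h. The 9 libraries fall into 3 groups of 3 by their titles: wild type with LPS (WT), Irg1 knockout with LPS (KO), and Irg1 knockout with LPS and 1 mM itaconate added 4 h after LPS. Irg1, also named Acod1, encodes the enzyme that makes itaconate from cis-aconitate. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

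Per the labels' protocols, messenger RNA was captured on oligo-dT beads and copied with barcoded oligo-dT primers. Barcoded samples were pooled, ligated to a second linker and amplified for strand-specific sequencing. Reads of such libraries lie mostly near the 3′ ends of transcripts, so they do not scale with transcript length. The protocols mention no molecular identifier, so reads that are copies of 1 molecule count separately. The authors deposited 1 table of raw read counts per gene, in whole numbers. Alignment with STAR and counting with HTSeq on the mm10 genome build are named in the submitters' processing notes. Their versions, the annotation release and any filters were not given in the sources used here. The description labels carry a number before the barcode, which is read here as the pool, although the labels do not define it. WT replicates 1, 2 and 3 and KO replicates 1 and 2 are in pool 1, KO replicate 3 and itaconate replicate 1 in pool 2, itaconate replicate 2 in pool 3 and itaconate replicate 3 in pool 4. On that reading pool and group are partly confounded.

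The table held 22165 gene rows under Ensembl identifiers and 5 summary lines of the counter. Symbols and GRCm38 positions were assigned to 21745 identifiers through a reference name table. The summary lines stayed out of library sizes and tests. Reads outside annotated genes made up 23.1% to 33.7% of the reads in a library, reads with several alignments 17.1% to 20.0%, and ambiguous reads 0.27% to 0.44%. Because reads with several alignments were set aside by the counter, near-identical genes such as ribosomal protein genes with pseudogenes, the H2 family and the Ifit and Oas families are measured less certainly. The overlapping genes mt-Nd4 and mt-Nd4l are likewise uncertain. Gene reads per library ranged from 7361671 to 20430359, at which 3 reads correspond to 0.147 to 0.408 CPM, which are counts scaled to a common library total. These limits cover counting error only.

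The counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (two-sided) in R 4.3.3. All 9 libraries entered 1 fit with group as the only term, after trimmed mean of M-values (TMM) scaling and the edgeR filter by expression with a minimum count of 10, which left 10781 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The test was checked on simulated counts made from the real means and library sizes, with 200 genes changed. For KO against WT, over 10620 genes, 75 of 100 genes changed 4-fold and 6 of 100 changed 2-fold were recovered, with 6 false calls. For itaconate against KO, over 10609 genes, the numbers were 75 and 7 with 0 false calls. For itaconate against WT, over 10607 genes, they were 76 and 10 with 5 false calls. CPM values in the text are scaled by TMM, and means are given ± SD over 3 libraries per group. Exceptions are sums over marker or receptor genes and genes below the filter, whose CPM are taken from raw gene reads without TMM.

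Gene lists were fixed before the data were examined, as were the 3 comparisons, the tests and the rule for named genes. There were 34 lists, of which 31 had at least 3 tested members. The 4 primary lists were type I interferon-stimulated genes, inflammatory cytokines, chemokines and effectors, NRF2 target genes, and ATF4 and integrated stress response genes. The others covered metabolism, organelles, antigen presentation, stress, the cell cycle, other cell types and checks of strain, sex and the Irg1 locus. Lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The Benjamini-Hochberg adjustment ran over the 31 lists of a comparison. Genes were named by rule: Irg1, called genes with at least 10 CPM whose groups did not overlap (up to 10 in each direction), the 4 members of each list with the smallest p, a fixed panel of 20 genes, and genes called with opposite sign in KO against WT and itaconate against KO. No gene met the second or the last part in the edgeR fit of all 9 libraries.

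The gene test was refitted under 22 other settings, 9 of which left out 1 library each. The others changed the scaling factors, the filter, the tool (DESeq2 1.42.0 or limma-voom), the libraries in the fit or the terms of the model. A fold threshold and a looser adjusted p were also tried. Another edgeR dispersion method and a fit without the 4 libraries whose Irg1 reads go against their labels were added after the data were seen, as were estimated correlations for the lists in that fit, in pool 1 alone and without WT replicate 1, WT replicate 2, KO replicate 3 or itaconate replicate 3. Replicate pairs within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 44 to 167.6, so each library was counted as 1 sample. Plots were drawn with matplotlib.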

Results

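RNA sequencing of LPS-treated macrophages addressed what loss of the itaconate-producing enzyme Irg1 does to gene expression, and what itaconate added to knockout cells does. The 9 libraries comprised 3 labelled WT, 3 labelled KO and 3 labelled KO with itaconate. Gene reads numbered 8164583, 12224652 and 7361671 in the libraries labelled WT replicates 1 to 3. They numbered 20430359, 12717604 and 10200503 in those labelled KO, and 10787063, 9466333 and 10374213 in those labelled itaconate.

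Irg1 (Acod1, ENSMUSG00000022126.6), on the plus strand of chromosome 14 from 103046977 to 103056573 in GRCm38, was measured first because it tests the genotype labels. Its reads went against the labels of 4 libraries. The libraries labelled WT replicates 1 and 2 held 94 and 117 Irg1 reads (11.3 and 9.14 CPM), whereas the library labelled WT replicate 3 held 31169 (4170 CPM). The libraries labelled KO replicates 1 and 2 held 154 and 170 reads (7.53 and 12.9 CPM), whereas the library labelled KO replicate 3 held 44920 (4420 CPM). The libraries labelled itaconate replicates 1 and 2 held 94 and 8 reads (8.68 and 0.877 CPM), whereas the library labelled itaconate replicate 3 held 60716 (6420 CPM). The lowest of the 3 high libraries lay 324-fold above the highest of the 6 low ones. By label, Irg1 averaged 1400 ± 2400 CPM in WT and 1480 ± 2550 CPM in KO (SD, n = 3), a log2 fold change of 0.08 ± 2.35 (SE) with an edgeR adjusted p of 0.999. The labels do not say which part of Irg1 was deleted, so reads near its 3′ end need not report the deletion. All groups below are as labelled, and every direction between them carries this conflict.

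**Figure D1:**
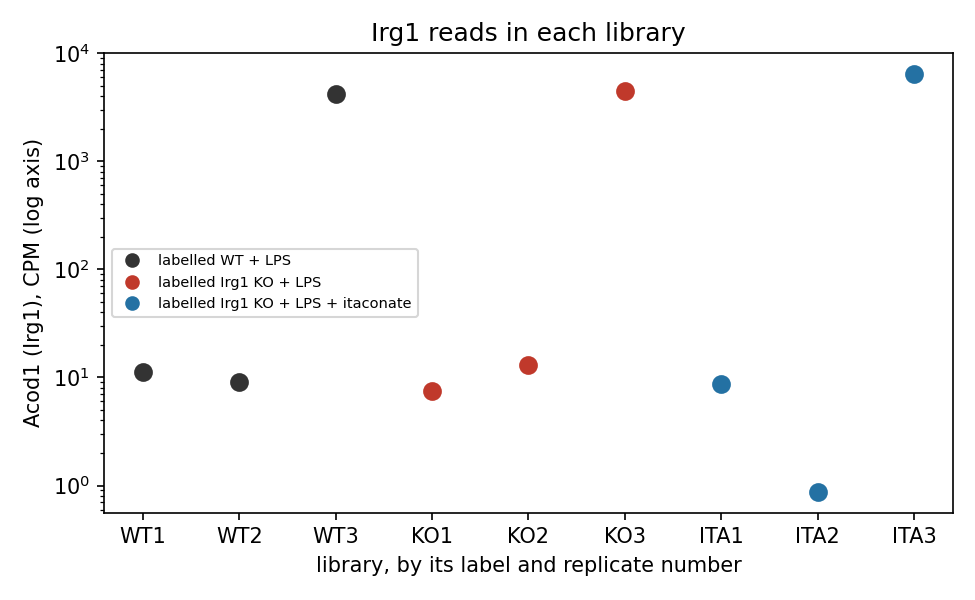
Irg1 (Acod1) in CPM on a log axis, 1 point per library, coloured by the labelled group. The libraries labelled replicate 3 lie between 4170 and 6420 CPM and the other 6 between 0.877 and 12.9 CPM, in each labelled group.

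The mean correlation of log2 CPM across genes was 0.945 over the 9 pairs of libraries within labelled groups and 0.942 over the 27 pairs between them. Of the 280 ways to form 3 groups of 3 libraries, 67 gave a difference at least as large as the labels (exact permutation test, one-sided p = 0.239). The library labelled itaconate replicate 3 stood apart, with a mean correlation of 0.909 with the other 8, against 0.939 to 0.954 for those. It had a score of 90.3 on the first principal component (32.6% of the variance), where the others lay between -23.6 and 2.9. It was the highest of the 9 libraries for 2140 genes and the lowest for 2801. Mitochondrially encoded genes took 0.71% of its gene reads, and 1.27% to 2.57% elsewhere.

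**Figure D2:**
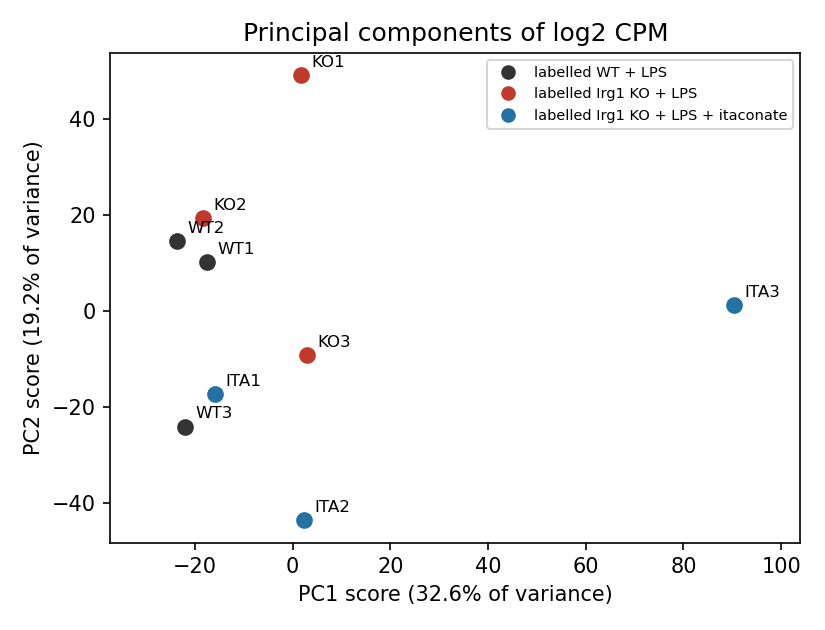
Scores of the 9 libraries on the first and second principal components of log2 CPM, coloured by the labelled group and named by label and replicate number. The library labelled itaconate replicate 3 sits at 90.3 on the first component, and the other 8 lie between -23.6 and 2.9.

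The comparison of the libraries labelled KO with those labelled WT asked what loss of Irg1 changes after LPS. No gene passed the edgeR threshold among 10781 tested (0 higher, 0 lower), and the smallest adjusted p was 0.99. At an unadjusted p under 0.05 there were 337 genes, where 539 are expected by chance. DESeq2 called 1 gene and limma-voom 0. The DESeq2 call was Snx6, a sorting nexin of endosomes, at a log2 fold change of 1.28 ± 0.26 (SE). It was named after its values were seen. The median SE of a log2 fold change was 0.35.

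No inflammatory gene passed between these labels. Il1b, the precursor of interleukin-1β, differed by -0.42 ± 0.28 on the log2 scale, Tnf by -0.42 ± 0.39 and Il6 by 0.72 ± 0.69. Nos2, the inducible nitric oxide synthase, differed by 0.73 ± 0.41, and Cxcl9, an interferon-γ-induced chemokine, by 0.83 ± 0.35. The inflammatory list had 12 of 29 members higher and a median log2 fold change of -0.12 (camera adjusted p = 0.572). That value turned on single libraries. It was -0.57 without the library labelled KO replicate 3 (adjusted p = 0.00139) and -0.22 without WT replicate 2 (adjusted p = 0.015). It was 0.19 without WT replicate 3 (adjusted p = 0.41) and 0.14 without KO replicate 1 (adjusted p = 0.288). Cxcl10 ranged from 39.8 to 316 CPM among the libraries labelled WT and from 43.7 to 431 CPM among those labelled KO. Type I interferon-stimulated genes had 20 of 50 members higher and a median of -0.17 (adjusted p = 0.572). The median was -0.32 without WT replicate 2 (adjusted p = 0.000362), -0.24 without KO replicate 3 (adjusted p = 0.0424) and 0.08 without WT replicate 1 (adjusted p = 0.123). Among them Xaf1 differed by 1.12 ± 0.38, Sp100 by 0.82 ± 0.34 and Isg15, a ubiquitin-like modifier, by -0.48 ± 0.42. The Isg15 value depends on KO replicate 3, which held 1430 Isg15 reads. KO replicates 1 and 2, with more gene reads, held 856 and 797. NRF2 targets, the antioxidant and detoxification genes, had 25 of 31 members lower and a median of -0.26 (adjusted p = 0.0879). Their median was -0.35 without WT replicate 1 (adjusted p = 0.0435), -0.39 without WT replicate 2 (adjusted p = 0.00624) and -0.42 without KO replicate 3 (adjusted p = 0.00288). Hmox1, the heme oxygenase, differed by -0.2 ± 0.31, Nqo1 by -0.63 ± 0.47 and Txnrd1 by 0.94 ± 0.36. ATF4 targets and integrated stress response genes had 23 of 34 members lower and a median of -0.15 (adjusted p = 0.362), with Atf4 itself at 1.11 ± 0.38. The Atf4 value rests on the library labelled KO replicate 2, at 1230 CPM where the other 2 labelled KO lay at 380 and 467 CPM, and was 0.41 without it. The values of Cxcl9 and Txnrd1 were 0.46 and 0.51 without KO replicate 1, and Nos2 was 1.27 without WT replicate 3. With an estimated correlation each of these 4 lists had an adjusted p = 0.858 without WT replicate 1, an adjusted p = 0.824 without WT replicate 2 and an adjusted p = 0.789 without KO replicate 3. Leaving out the 4 libraries that go against their Irg1 labels, a choice made after the data were seen, keeps 1 library labelled WT, replicate 3. It was kept for its Irg1 reads, a gene that LPS induces, and the other groups supply its spread. The medians against that library were -0.8 for inflammatory (adjusted p = 6.16e-10), -0.17 for interferon-stimulated (adjusted p = 0.0102), -0.66 for NRF2 (adjusted p = 6.06e-06) and -0.37 for ATF4 genes (adjusted p = 0.0167). With an estimated correlation each had an adjusted p = 0.741. Ifnb1, which encodes interferon-β, was below the filter, with 1, 0 and 2 reads in the libraries labelled WT, 0, 4 and 6 in those labelled KO and 17, 6 and 22 in those labelled itaconate. Its means were 0.131 ± 0.136, 0.301 ± 0.294 and 1.44 ± 0.752 CPM (SD, n = 3). Without a filter edgeR gave Ifnb1 log2 fold changes of 2.36 ± 1.43 for itaconate against KO and 3.55 ± 1.58 for itaconate against WT (adjusted p = 0.605 and 0.461).

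Of the other lists, 4 passed camera at its preset correlation, with lower values in the libraries labelled KO. In the nuclear-encoded respiratory chain 62 of 74 members were lower, with a median of -0.25 (adjusted p = 9.14e-05). In glycolysis 19 of 22 were lower (median -0.19, adjusted p = 0.00859), including Hk1, a hexokinase, at -1.08 ± 0.32. Cytosolic ribosomal proteins had 62 of 82 lower (median -0.22, adjusted p = 0.00764), and macrophage identity genes 15 of 18 (median -0.28, adjusted p = 0.0399), with Csf1r, the receptor of macrophage colony-stimulating factor, at -0.47 ± 0.34. The respiratory chain list was called whichever library was left out, at -0.15 without KO replicate 1 (adjusted p = 0.0151). Glycolysis was not called without WT replicate 3 (-0.12, adjusted p = 0.132) or KO replicate 1 (-0.13, adjusted p = 0.207), and was -0.31 without WT replicate 1 or KO replicate 2. Ribosomal proteins were not called without WT replicate 2 (adjusted p = 0.0786) or KO replicate 2 (adjusted p = 0.11). Macrophage identity was not called without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3 (adjusted p = 0.123, 0.0869, 0.11 and 0.125). Without the 4 libraries that go against their Irg1 labels neither of these last 2 lists was called (adjusted p = 0.246 and 0.644). None of the 4 was called with an estimated correlation (adjusted p = 0.788 for each) or by fry (adjusted p = 0.919 for each). No member of any list passed when adjusted over the list alone. Within pool 1, which holds 3 libraries labelled WT and 2 labelled KO, edgeR called 0 genes and camera at the preset correlation 8 lists. Those included the 4 primary ones, with the inflammatory median at -0.57 (adjusted p = 0.00275). With an estimated correlation the interferon list had an adjusted p = 0.848 there and the other 3 primary lists an adjusted p = 0.788. Pool 1 leaves out the high-Irg1 library labelled KO replicate 3 but keeps the 2 low-Irg1 libraries labelled WT.

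The comparison of the libraries labelled itaconate with those labelled KO asked what itaconate does in cells that lack the enzyme. No gene passed the edgeR threshold among 10781 (smallest adjusted p = 0.51). At an unadjusted p under 0.05 there were 895 genes, where 539 are expected by chance. Of the 10 ways to split these 6 libraries 3 against 3, 5 gave at least as many, the labelled one included. DESeq2 called 12 genes, 4 higher and 8 lower, and limma-voom 0. Mitochondrially encoded genes were the only list past camera at its preset correlation: 11 of 13 were lower, with a median of -0.52 (adjusted p = 1.25e-05). Adjusted over the list alone, 4 members passed by edgeR, whereas none did over all genes in that fit. Over all genes DESeq2 called mt-Nd4l (adjusted p = 0.0488), and edgeR without a filter on low counts called mt-Nd4l and mt-Nd5 (adjusted p = 0.0032 for each). Without the 4 libraries edgeR called mt-Nd5 (adjusted p = 0.0171) and mt-Nd2 (adjusted p = 0.0496). The 4 were mt-Nd5 (-1.89 ± 0.51), mt-Nd4l (-1.76 ± 0.43), mt-Nd2 (-1.23 ± 0.32) and mt-Nd4 (-1.16 ± 0.33), all subunits of respiratory complex I. With an estimated correlation the list had an adjusted p = 0.602, and by fry an adjusted p = 0.328. Without the library labelled itaconate replicate 3 the median was -0.33 (adjusted p = 0.0226, and adjusted p = 0.958 with an estimated correlation), and without itaconate replicate 1 it was -0.93. The mt-Nd4l value was -1.11 without KO replicate 3. With the pool as a term the median of the list was 0.04 (camera adjusted p = 0.257), and that fit compares only the 2 libraries of pool 2. That pair was labelled itaconate replicate 1 and KO replicate 3.

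Of the primary lists in this comparison, interferon-stimulated genes had 27 of 50 members higher and a median of 0.07 (adjusted p = 0.657). Isg15 differed by 1.15 ± 0.43, Bst2, a restriction factor for enveloped viruses, by 0.88 ± 0.31, and Stat2 by 0.8 ± 0.36. Inflammatory genes had 15 of 29 higher and a median of 0.02 (adjusted p = 0.657). Without the library labelled KO replicate 3 that median was 0.5 (adjusted p = 0.00886, and adjusted p = 0.817 with an estimated correlation). Without the 4 libraries that go against their Irg1 labels it was 0.35 (adjusted p = 0.000101), and the interferon and NRF2 medians were 0.24 and 0.32 (adjusted p = 0.012 for each). With an estimated correlation these 3 had an adjusted p = 0.988. In both fits the libraries labelled KO are all from pool 1 and those labelled itaconate from other pools. Cxcl9 differed by -1.43 ± 0.35 and was called adjusted over the list alone (adjusted p = 0.0294) but not over all genes (adjusted p = 0.507). Over all genes it was called when low counts were left unfiltered (adjusted p = 0.0162) and without the 4 libraries (-1.8 ± 0.36). Nos2 differed by -0.99 ± 0.42, Il1b by -0.02 ± 0.28 and Il6 by -0.07 ± 0.67. NRF2 targets had 20 of 31 higher (median 0.13, adjusted p = 0.55), with Hmox1 at 0.76 ± 0.32 and Gclm at 0.06 ± 0.28. ATF4 and stress response genes had 16 of 34 higher (median -0.07, adjusted p = 0.99), with Atf4 at -1.03 ± 0.38, or -0.33 without KO replicate 2. Isg15 was 1.81 without KO replicate 3, and Stat2 0.33 without itaconate replicate 3. Among negative regulators of inflammation, 15 of 19 were higher (median 0.35, adjusted p = 0.173). That list was called without KO replicate 3 (0.53, adjusted p = 0.0356), without itaconate replicate 3 (0.37, adjusted p = 0.0486) and without the 4 libraries (0.52, adjusted p = 0.00423). These had an adjusted p = 0.817, 0.958 and 0.988 with an estimated correlation. Its median was 0.15 without KO replicate 1, 0.22 without itaconate replicate 1 and 0.04 with the pool as a term. Tnfaip3, which encodes the ubiquitin-editing enzyme that restrains NF-κB, was 29.6 ± 13.7 CPM in the libraries labelled KO and 79.1 ± 34.3 CPM in those labelled itaconate (SD, n = 3). Its log2 fold change of 1.42 ± 0.39 was called adjusted over the list alone (adjusted p = 0.0422) and over all genes only without a filter on low counts (adjusted p = 0.0314).

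**Figure D3:**
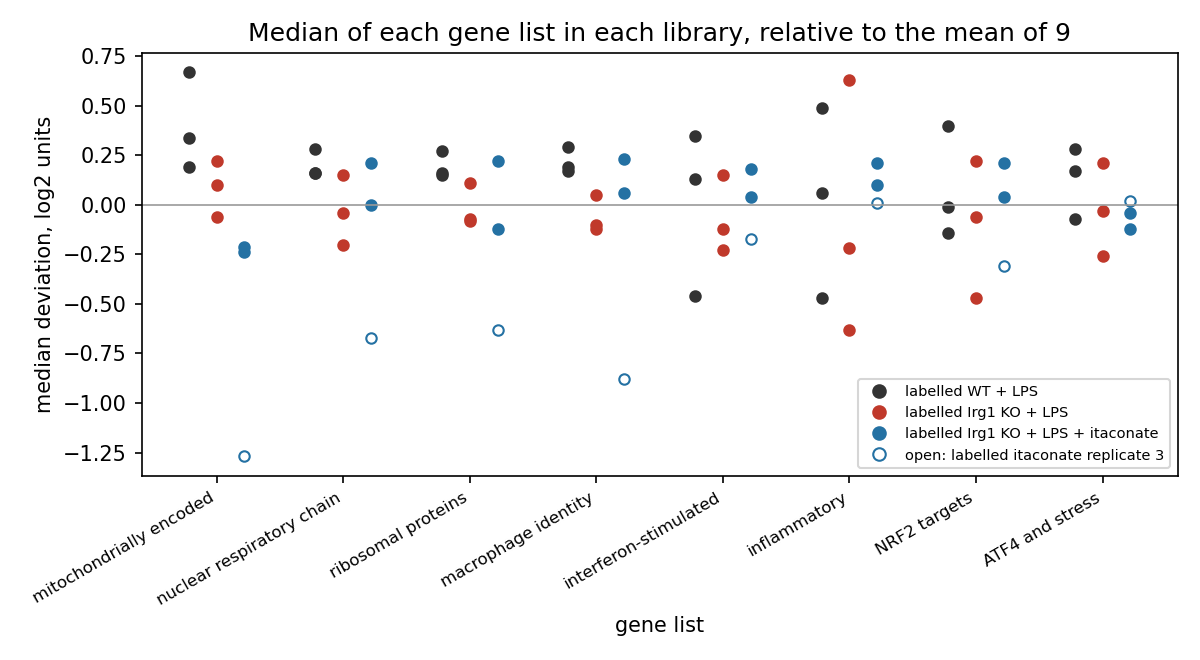
Median deviation of each list's members from their mean over the 9 libraries, in log2 units, for 8 gene lists, 1 point per library, coloured by the labelled group. The open point is the library labelled itaconate replicate 3, at -1.27 for mitochondrially encoded genes, where the other 2 libraries labelled itaconate lie at -0.24 and -0.21.

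The comparison of the libraries labelled itaconate with those labelled WT asked how far treated knockout cells differ from wild type. No gene passed the edgeR threshold (smallest adjusted p = 0.49). At an unadjusted p under 0.05 there were 958 genes, where 539 are expected by chance. DESeq2 called 17 genes and limma-voom 0. All 13 mitochondrially encoded genes were lower, with a median of -0.84 (camera adjusted p = 1.63e-08 at the preset correlation). Adjusted over the list alone 8 of them passed, among them mt-Nd4 (-1.37 ± 0.33), mt-Cytb (-1.32 ± 0.45) and mt-Co1 (-0.63 ± 0.25). Over all genes DESeq2 called mt-Nd4 (adjusted p = 0.0402). Without a filter on low counts edgeR called mt-Nd4 and mt-Nd5 (adjusted p = 0.027 and 0.00496). Cytosolic ribosomal proteins (69 of 82 lower, median -0.34, adjusted p = 9.76e-06) and the nuclear-encoded respiratory chain (60 of 74 lower, median -0.3, adjusted p = 1.6e-05) were also called. So was the list of MHC class II and costimulation genes (11 of 11 lower, median -0.41, adjusted p = 0.0335), with H2-Ab1 at -0.82 ± 0.33. With an estimated correlation the mitochondrially encoded list had an adjusted p = 0.295 and the other 3 an adjusted p = 0.693. Without the library labelled itaconate replicate 3 only the mitochondrially encoded list was called at the preset correlation, and the medians of the ribosomal, respiratory chain and MHC class II lists were -0.15, -0.11 and -0.21. Without itaconate replicate 1 the first 2 were -0.58 and -0.5. The MHC class II list was also not called without WT replicate 3 (adjusted p = 0.0643) or itaconate replicate 2 (adjusted p = 0.0622). No pool holds libraries of both labels, so no value within a pool exists.

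The primary lists in this comparison had medians of -0.03 for interferon-stimulated, -0.04 for inflammatory, -0.07 for NRF2 and -0.18 for ATF4 genes, and none was called (adjusted p = 0.874, 0.896, 0.896 and 0.495). For the first 2 of these lists the mean was positive, at 0.02 and 0.07, and camera's direction was up. The interferon median was 0.22 without WT replicate 1 (adjusted p = 0.0264, and adjusted p = 0.762 with an estimated correlation). Without the 4, where WT replicate 3 is again the 1 library with that label and other groups supply the spread, the inflammatory, NRF2 and ATF4 medians were -0.25, -0.31 and -0.28 (adjusted p = 0.0312 for each, and adjusted p = 0.911 for each with an estimated correlation). Cebpb, a transcription factor of the inflammatory response, differed by 1.45 ± 0.46 and Ptgs2, the inducible cyclooxygenase, by 1.39 ± 0.63, or 0.58 without itaconate replicate 3. Adjusted over the list alone, Txnip (1.21 ± 0.34) passed in the inflammasome list. Tap2, a peptide transporter (1.38 ± 0.37), and H2-T23 (-3.15 ± 0.85) passed in the list of MHC class I antigen presentation. Over all genes edgeR called Tap2, H2-T23 and Cebpb when low counts were left unfiltered (adjusted p = 0.0391, 0.000225 and 0.0402). The H2-T23 value rests on the library labelled WT replicate 2, at 88.7 CPM, where the other 8 lay between 2.08 and 9.6 CPM.

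Whether itaconate moved genes opposite to the knockout was measured by the correlation, across 10781 genes, of the log2 fold changes of KO against WT and of itaconate against KO. Pearson's r was -0.33 and Spearman's rho -0.29. Because both comparisons share the libraries labelled KO with opposite sign, simulations without any effect gave -0.49 and -0.47. The covariance was -0.08, against -0.1 simulated. Of 100 random regroupings of the 9 libraries, 88 gave an r at or below the observed one. With no library shared between the comparisons r was 0.05. By edgeR with all 9 libraries no gene was called in both comparisons. DESeq2 called Snx6 in both, at 1.28 ± 0.26 for KO against WT and -1.23 ± 0.26 for itaconate against KO. Without the 4 libraries edgeR called Cfb in both. Both genes changed in opposite directions, and the comparisons share their libraries labelled KO. Genes are not independent replicates.

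Each count was repeated without the 4 libraries whose Irg1 reads go against their labels, a choice made after the data were seen. It leaves 1 library labelled WT, assumed to vary like the others, 2 labelled KO and 2 labelled itaconate. Irg1 reads cannot tell KO from KO with itaconate. The choice therefore does not check which of the libraries labelled KO or itaconate received itaconate. edgeR then called 2 genes for KO against WT, namely Acod1 (-8.66 ± 0.71) and Cfb, which encodes complement factor B (7.18 ± 1.23) and was named after its values were seen, and only Acod1 (-9.73 ± 0.75) for itaconate against WT. The Acod1 calls follow from the choice of libraries by their Irg1 reads. It called 217 genes for itaconate against KO, 56 higher and 161 lower. Among the higher genes were Cxcl10 (1.98 ± 0.39), Isg15 (1.77 ± 0.38) and Mt1, a metallothionein (2.25 ± 0.37). Cfb had the smallest adjusted p, at -4.98 ± 0.7 (adjusted p = 0.00358). It was 35.43 and 5.67 CPM in the libraries labelled KO replicates 1 and 2, 0.13 CPM in WT replicate 3 and 12.72 CPM in WT replicate 1, which that fit leaves out. Among the other lower genes were Cxcl9 (-1.8 ± 0.36) and Mki67, a proliferation marker (-2.83 ± 0.46). Mki67 does not stand for the cell cycle list. In the fit of all 9 libraries 15 of its 22 members were higher and 7 lower (median 0.27, camera adjusted p = 0.657). The annotated gene span, compared after these calls were seen, had a median of 38.9 kb for the 161 lower genes, 5.77 kb for the 56 higher genes and 24.2 kb for the 11314 tested genes with a position. Across genes, which are not independent replicates, a library's deviation from the others correlated with gene span at 0.24 and -0.01 (Spearman) for the libraries labelled KO replicates 1 and 2. For itaconate replicates 1 and 2 the values were -0.26 and 0. Reads outside annotated genes made up 28.4% and 26.9% in those labelled KO and 23.1% and 26.3% in those labelled itaconate. In that comparison both libraries labelled KO are from pool 1 and those labelled itaconate are from pools 2 and 3. Pool and treatment cannot be told apart there.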

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

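Of the tests on this library, those of chemosensory receptor genes and of the pool were chosen only after the result was seen. The others were chosen before their values were computed, when high reads of the repeat-rich gene models Gm10800, Gm10801 and Gm21738 in this library had already been seen.

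Reads outside annotated genes made up 33.7% of the reads in the library labelled itaconate replicate 3. They made up 24.4% to 25.6% in the libraries labelled WT and at most 28.4% in the other 8. These reads enter none of the comparisons. The same library stands apart on the first principal component and carries the lowest mitochondrial share. Library size does not account for it: thinned to the 7361671 reads of the smallest library, its mean correlation with the others was still 0.029 below the lowest of theirs (a difference of -0.029). A first test of reads from genomic DNA or unspliced RNA was void. Its set of gene families included cystatins, and Cst3, which macrophages express, held 95.1% of the set's reads, so the ratio of 0.742 to the highest other library measures that gene. Restricted afterwards to 1358 olfactory, vomeronasal and trace amine receptor genes, these genes summed to 135 CPM of raw gene reads, 4 times the highest of the other 8 libraries (33.8). After thinning, 49 of these genes had a read, against 11 to 23 elsewhere. Before thinning, its 1403 receptor reads lay on 50 of the 1358 genes, and the 500 of KO replicate 1 on 16. Whether single genes carry these sums was not checked, unlike in the first set. The library's deviation correlated with gene span at 0.24 across genes, but so did that of KO replicate 1 (0.24), whose receptor genes summed to 24.5 CPM. Reads from genomic DNA or unspliced RNA remain a candidate explanation, chosen and tested on the same data. Pool 4 holds 1 library, this one, so the pool cannot be told apart from it. The library labelled itaconate replicate 2 came next in mean correlation (0.939), mitochondrial share (1.27%) and receptor reads (33.8 CPM), whereas itaconate replicate 1 lay among the rest (0.946, 1.73% and 19.4 CPM). An effect of itaconate stays open and was not tested.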

How the results depend on the processing

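Of the alternatives, another edgeR dispersion method, the omission of the 4 libraries whose Irg1 reads contradict their labels, and estimated correlations in 6 reduced fits were chosen after the data were seen. At the depth, spread and number of these libraries the test recovered 6, 7 and 10 of 100 simulated 2-fold changes in the 3 comparisons, and which of these limits it was not tested. The counts of called genes for KO against WT, itaconate against KO and itaconate against WT stayed at 0 under the following settings. These were 3 other scalings, limma-voom, the filter at 10 CPM, the pool as a term, the fit of only the compared groups and the other dispersion method. Both thresholds also gave 0, which tests nothing. They reuse the main fit, whose smallest adjusted p values by edgeR were 0.99, 0.51 and 0.49. DESeq2 gave 1, 12 and 17. Without a filter on low counts edgeR gave 0, 80 and 92. Without the 4 contradicting libraries it gave 2, 217 and 1. Leaving out 1 library each gave 0 to 0, 0 to 6 and 0 to 4, and the calls appeared without the library labelled itaconate replicate 1 (6 and 4). The cause was not tested.

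Across genes no general pairing of samples by replicate number was seen, although this check cannot exclude a shared animal or batch. Deviations of same-numbered libraries correlated between -0.16 and 0.24, with 2 of 9 pairs above 0.1, and 4 of 9 libraries matched their own number best. The highest value of all pairs, 0.24, was that of WT replicate 3 and KO replicate 3. With the replicate block edgeR called 0, 0 and 0 genes, and a test of the number itself called 1 gene, Acod1. With the block camera called 4, 1 and 5 lists, against 4, 1 and 4 without it.

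Lists called at the preset correlation numbered 4, 1 and 4. With an estimated correlation and with fry they numbered 0, 0 and 0. With the pool as a term they numbered 9, 0 and 6, in pool 1 alone 8 (KO against WT), at a mean of at least 10 CPM 7 (itaconate against WT), and without the 4 contradicting libraries 10, 9 and 7. Leaving out 1 library gave 2 to 7, 1 to 4 and 1 to 8. For KO against WT the extremes came without the libraries labelled KO replicate 2 (2) and replicate 3 (7). For itaconate against KO they were 4 without KO replicate 3, 3 without itaconate replicate 1 and 2 without itaconate replicate 3. For itaconate against WT they were 8 without WT replicate 1 and 1 without itaconate replicate 3. The mitochondrially encoded list in itaconate against KO turned to a median of 0.04 with the pool as a term (adjusted p = 0.257). The interferon-stimulated list in itaconate against WT turned to 0.22 without WT replicate 1 (adjusted p = 0.0264), and leaving out 1 library moved it between -0.22 and 0.22. With 1 library of the comparison left out, the primary lists gave 24 medians per comparison, of which 7, 1 and 1 were called and 3, 6 and 6 changed sign. In KO against WT the inflammatory list turned from -0.12 to 0.19 without WT replicate 3 and 0.14 without KO replicate 1, and the interferon list from -0.17 to 0.08 without WT replicate 1, none of them called. Called there were NRF2 targets without WT replicates 1 and 2 and KO replicate 3 (adjusted p = 0.0435, 0.00624 and 0.00288), and the interferon and inflammatory lists without WT replicate 2 or KO replicate 3. With an estimated correlation none of these primary lists was called in the same fits, in any of the comparisons. The cause was not tested.

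The Irg1 log2 fold changes of 0.08, 0.53 and 0.62 follow which libraries are in the fit, since 3 hold nearly all Irg1 reads. With the pool as a term they were -7.1, -8.99 and -16.09, in pool 1 alone -7.07, and without the 4 contradicting libraries -8.66 (KO against WT) and -9.73 (itaconate against WT), past the threshold because those libraries were left out for their Irg1 reads. Leaving out 1 library gave -7.07 to 7.18, -8.24 to 7.72 and -8.14 to 7.71, with the extremes without the libraries labelled replicate 3. The correlation of -0.33 between the knockout and itaconate changes was 0.05 with no shared library, where itaconate was set against KO replicate 3 alone. It was -0.36 at a mean of at least 10 CPM and -0.53 to -0.18 when leaving out 1 library. The lowest came without KO replicate 3 and the highest without itaconate replicate 1. Of the values of the other named genes, 29 passed the threshold only under another setting and 0 changed sign while called, whereas Irg1 did so in 2 comparisons without the 4 libraries.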

Other observations

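Tests of the Irg1 labels and of a single deciding library were chosen only after the results were seen. The tests of other splits and of the pool as a term for mitochondrially encoded genes were chosen before. That the pool test decides nothing, because it rests on 1 library of each label, was settled after its value was seen, as was leaving wrong labels and the LPS response open.

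Sums over markers are given in CPM of raw gene reads, without TMM scaling. Neutrophil markers summed to 374.8 to 456 CPM in the libraries labelled WT and 266.8 to 404.1 CPM in those labelled itaconate. T, B and NK cell markers summed to 1.6 to 3.2 CPM in all 9. Macrophage identity genes summed to 7384.4 CPM in the library labelled itaconate replicate 3 and 10353 to 15157.3 CPM in the other 8. Dendritic cell markers summed to 1087.7 CPM in that library and 680.6 to 969.1 CPM in the other 8, with itaconate replicate 2 next at 969.1 CPM. The Y-linked gene Uty was read in every library, at 25.7 to 40.9 CPM. Kctd12, which lies near Irg1 on chromosome 14 and was picked out after its values were seen, reached 263, 262 and 284 CPM in the 3 high-Irg1 libraries and 52.5 to 142 CPM in the other 6.

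Irg1 reads go against the labels of 4 libraries, on both sides: 2 labelled WT were low and 2 of the knockout genotype were high. Irg1 had a 7319-fold range among the 6 libraries labelled with the knockout genotype, the lowest of which held 8 reads. If those labels hold, the range argues against reads of a knockout allele outside its deleted part as the source of the high values. If labels are wrong, it does not bear on that explanation. A weaker or absent response to LPS in the libraries labelled WT replicates 1 and 2 stays open. In the mean of those 2 libraries, 25 of 29 other inflammatory genes were lower than in WT replicate 3. The median difference of these genes was -0.6 log2 units (quartiles -0.94 and -0.33), against -8.66 for Irg1. No untreated library analysed here sizes a lost response. Taken singly, WT replicates 1, 2 and 3 had inflammatory medians of 0.06, -0.47 and 0.49 against the mean of all 9 libraries. Their interferon-stimulated medians were 0.35, -0.46 and 0.13, so WT replicate 1 was not lower there. The inflammatory median followed Irg1 in the libraries labelled KO (-0.63, -0.22 and 0.63 for replicates 1 to 3) but not itaconate (0.21, 0.1 and 0.01). Wrong labels also stay open, because the 4 libraries out of place are the observation itself and nothing else measured here reads the deletion. The 3 high and 6 low libraries equal in number the 3 labelled WT and the 6 of the knockout genotype. Agreement with Irg1 does not show that the other titles are right. The list of genes beside Irg1 had adjusted p of 0.572, 0.657 and 0.896 in the 3 comparisons. It was called under 1 setting, for itaconate against WT without the 4 libraries (median -0.13, adjusted p = 0.0183, and 0.911 with an estimated correlation), a fit chosen by the Irg1 reads. All 3 high libraries carry replicate number 3, and they come from 3 different pools. No biological explanation was tested, because no labelled group separates these libraries.

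Mitochondrially encoded genes were lower in the libraries labelled itaconate than in those labelled KO. At camera's preset correlation the call does not need the library that stands apart: without itaconate replicate 3 the adjusted p was 0.0226. With an estimated correlation the list was called neither with that library (adjusted p = 0.602) nor without it (adjusted p = 0.958). That version therefore cannot decide whether 1 library makes the difference. Over the alternatives the camera adjusted p ranged from 4.47e-07 to 0.988, the latter with an estimated correlation and the 4 contradicting libraries left out. The pool remains open. With the pool as a term the median was 0.04, as the pool would predict, but that value rests on 1 library of each label in pool 2. In that pair 6 of 13 members were lower in the library labelled itaconate replicate 1. The other library, labelled KO replicate 3, goes against its Irg1 label. An effect of itaconate may also remain, and these libraries do not tell it apart from the pool.

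Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. Since the real counts were 0 genes, all 10 splits reach them in each comparison by construction, which tests nothing. The highest other split gave 2 genes for KO against WT, 1 for itaconate against KO and 0 for itaconate against WT. At an unadjusted p under 0.05 the real splits gave 337, 895 and 958 genes and the highest others 781, 1304 and 895. Counting the real split, 5, 5 and 1 of the 10 splits gave at least as many such genes. The split with 1304 set the libraries labelled KO replicates 1 and 2 (pool 1) with itaconate replicate 3 against the libraries of pools 2 and 3.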
